A study of Mus musculus with 12 samples.

How the data were processed

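Cultured hippocampal slices of C57BL/6J mice of mixed sex were incubated for 2 h in Control ACSF, IS, ACSF + DIDS or IS + DIDS, per the labels. Total RNA was extracted with a Qiagen RNeasy kit, and 100 ng of it was amplified and biotinylated with the Illumina TotalPrep kit, per the labels' protocols. Samples were hybridised singly to Illumina mouse whole-genome bead arrays, 12 in all with 3 per group.

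The scanner files hold, per the file headers, bead-averaged signal intensity exported from BeadStudio 2.3.47 with no normalization and no error model, 1 array per file. The submitters' processing notes name BeadStudio 2.0. Their values are linear and not background subtracted. The detection score is a fraction between 0 and 1 per the file headers and their values, near 1 for a probe above the negative controls. The files also give bead spreads and bead numbers as other measures, per the file headers. The value table that the authors deposited holds intensity for 46301 probes on a linear scale, not background subtracted. Its columns have nearly the same quartiles, at 63.1 to 63.6, 80.6 to 82.5 and 251.3 to 259.0. It was therefore taken to have been normalized between arrays before it was deposited, by a method that is not stated.

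Each value column was set against each scanner file. The scanner files of IS 2, ACSF + DIDS 1 and IS + DIDS 1 hold the same signals as those of ACSF + DIDS 3, IS + DIDS 2 and IS + DIDS 3, over 46628 probes. Value columns followed the sample's own scanner file for 9 arrays, with Spearman correlations of 0.997 to 1. For the remaining 3 arrays the correlation was 0.953 to 0.955, so those columns are values of arrays whose scanner values were not used here. The planned fit was on scanner intensities of all 12 arrays after neqc, which these 3 files rule out. The fit reported is on log2 of the deposited values instead, a departure made after the files were examined and before any group was compared. For the 3 arrays that rest on the value table alone, a detection score was not available.

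Per array, the median deposited value was 80.6 to 82.5. The median scanner intensity was 69.5 to 83.6, and 131.9 on IS 1. Of the probes, 43.7% to 45.5% were detected, and 40.3% on IS 1, with a median of 35 to 36 beads per probe. The mean correlation of an array with the other arrays was 0.989 to 0.991, and 0.983 for IS + DIDS 1. Precision is limited by the number of arrays.

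Samples were grouped by title. The description of ACSF + DIDS 2 names another group, IS + DIDS, and an alternative follows the description. Bead spreads are written on different scales in 2 sets of 6 files, which gives 2 export sets. Set A holds Control ACSF 1 and 2, IS 1 and 2, ACSF + DIDS 1 and IS + DIDS 1, and set B holds the others. For the 9 arrays with their own file the sets match the slide in the headers. For IS 2, ACSF + DIDS 1 and IS + DIDS 1 the slide is not known, and their set was read from files that hold signals of other arrays. The set A arrays of known slide are of Control ACSF and IS alone. With these sets, both hold all 4 groups, and results are given with the set as a block and within each set, but for DIDS they rest on this assignment. The values do not settle it: the deviation of ACSF + DIDS 1 from its group had a correlation of 0.08 with the difference between sets among the controls and -0.02 with that between IS 1 and IS 3, and that of IS + DIDS 1 0.29 and 0.13.

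A probe was kept where its detection score was at least 0.95 on at least 3 of the 9 arrays, which left 21554 probes. No annotation of the probes was given. Zero-padded numbers in probe names were read as NCBI gene IDs and matched to the RefSeq gene table for assembly GRCm38.p6. Of 11857 such probes, 9796 matched, and 9 more were named through an accession. This gave 9805 probes with a symbol, for 8106 genes, and left 36496 without. As a check, in a sparse range of IDs 80.2% of the padded numbers were gene IDs, against 2.87% of all integers. Unpadded numbers matched no more often than chance (2.02% against 1.96%) and were not used. Pairs of probes with the same gene ID had a median correlation of 0.32 over arrays (682 pairs), against -0.01 for 4999 random pairs. For a gene with several probes, the one with the highest mean was used, which left 20749 features. Where another probe of a named gene that passed had an unadjusted p of 0.05 or more, its value is given.

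Log2 intensities were fitted with limma 3.58.1 (lmFit with 1 mean per group and eBayes, all 12 arrays) in R 4.3.3, with other steps in Python 3.11.15. The 4 comparisons of 2 groups and the interaction were tested with 2-sided moderated tests and Benjamini-Hochberg adjustment over all features, at a threshold of 0.05. A gene not above background on any array of a group has only a bound there, "at least N-fold". The bound compares the mean log2 value of the brighter group with the dim group's mean of, per array, the higher of the probe's value and the lowest value among detected probes. For the 3 arrays without scanner values, the floor was the mean of those of the 9 others. Each of 31 gene lists was fixed before the data were examined, as were the groups, tests and most alternatives. Camera tested the 28 lists with at least 3 tested genes, with a preset correlation of 0.01. Interneuron, endothelial and blood cell markers had fewer. Of the 18 list calls, 3 held with an estimated correlation, all of them of immediate early genes.

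Named genes followed a rule fixed in advance. It takes up to 8 rises and 8 falls by size among genes that passed and whose groups did not overlap, up to 4 members of each list that passed, and a few genes in every comparison. Predicted gene symbols were passed over (2 in IS + DIDS against IS and 4 in IS + DIDS against ACSF + DIDS). Further list members such as Egln3 and features without a symbol were named after their values were seen. Covariances between comparisons that share arrays were set against 50 simulated data sets of unchanged groups.

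The fit was tested on simulated data of 20749 features with 200 changed. At a 2-fold change it recovered 77.6% of changed features in IS against Control ACSF, 88.1% in IS + DIDS against IS, 77.6% in IS + DIDS against ACSF + DIDS, 88.1% in ACSF + DIDS against Control ACSF and 58.2% in the interaction. At a 1.5-fold change it recovered 47.8%, 41.8%, 40.3%, 46.3% and 14.9%. Wrong calls were 7.45%, 4.97%, 5.96%, 4.32% and 0.893% of all calls.

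The alternatives were no filter, only probes detected on all 9 arrays, every probe on its own, only the 2 groups compared, the export set or the replicate number as a block, ACSF + DIDS 2 moved to IS + DIDS, an intensity-dependent prior, a 1.5-fold threshold and each array left out in turn. Scanner values of the 9 arrays were run with quantile normalization, and with background correction and median scaling. The estimated correlation was an alternative for the lists. Added after the data were seen were neqc on the 9 arrays, the deposited values of the 9 arrays, the export set as a block without IS + DIDS 1, normexp correction and a second quantile normalization of the deposited values.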

Results

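RNA levels were measured on 12 arrays of mouse hippocampal slices kept in culture, with 3 arrays in each of 4 groups. Slices lay for 2 h in artificial cerebrospinal fluid (Control ACSF), in an ischemic solution (IS), in artificial cerebrospinal fluid with DIDS (ACSF + DIDS), or in the ischemic solution with DIDS (IS + DIDS). DIDS is a stilbene disulfonate that blocks anion channels and bicarbonate exchangers. After filtering, 20749 features were tested, of which 5092 were genes with a symbol and 15657 were probes without one. The 12 arrays had median intensities of 80.6 to 82.5 in the deposited values. On the 9 arrays with scanner values of their own, 40.3% to 45.5% of probes were detected, and IS 1 was the lowest. Nothing in the labels says whether replicates came from separate cultures or animals, so the p-values measure the spread between these samples. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.14 for a comparison of 2 groups.

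**Figure D1:**
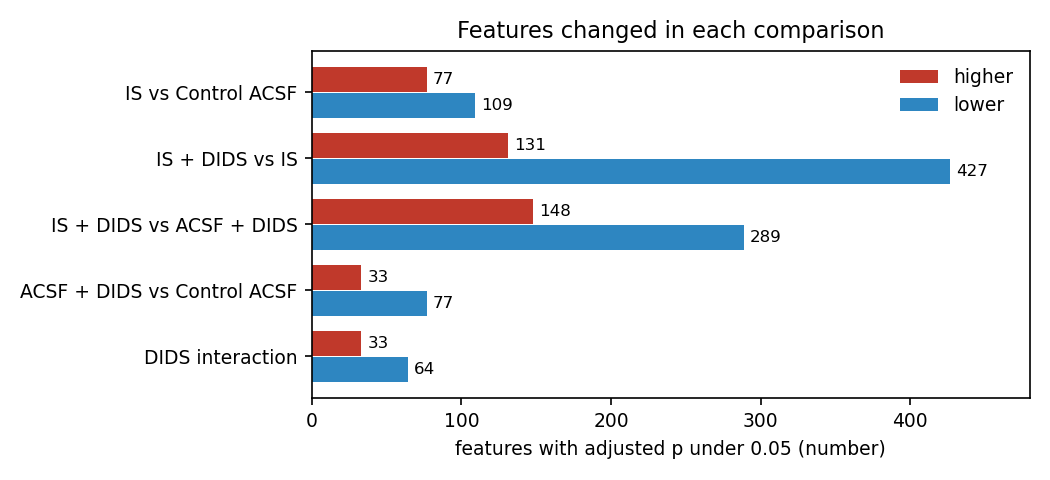
Number of features that passed the threshold (adjusted p under 0.05) in each comparison, split into higher and lower levels. IS + DIDS against IS had the most, 131 higher and 427 lower.

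The comparison of IS with Control ACSF asks what the ischemic solution alone did to the slices. The chemokine receptor-like gene Ccrl2 and Ptgs2, which encodes cyclooxygenase 2, rose most among the named genes. Adamts1, a secreted metalloprotease gene, Ptx3, which encodes a soluble pattern recognition protein, and the monocyte chemokine gene Ccl2 fell. Transcription factor genes of the early response went both ways: Klf2 and Klf4 rose, and Egr2 fell.

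Ccrl2 rose by a log2 fold change of 4.03 (SE 0.46, adjusted p = 0.000993), from a mean intensity of 247 to 4860. Its rise was 4.70 in set A and 2.67 in set B, the 2 sets in which the arrays were exported. For IS 2, and for the only arrays of both DIDS groups in set A, the set was read from files that hold signals of other arrays, so all values by set that involve DIDS rest on an assignment that was not verified. Ptgs2 rose by 2.75 (SE 0.41, adjusted p = 0.00582), by 3.39 in set A and 1.46 in set B. Cytip rose by 1.68 and Ccn1, a matrix protein gene, by 1.55 (adjusted p = 0.000118 for each). Arrdc3 rose by 1.15, Klf2 by 1.11, Klf4 by 1.02 and Mest by 0.86. Adamts1 had a log2 fold change of -1.81 (SE 0.11, adjusted p = 1.88e-05), Egr2 of -1.81 (SE 0.22, adjusted p = 0.00115), Ptx3 of -1.65 (SE 0.14, adjusted p = 0.000118) and Ccl2 of -1.41 (SE 0.18, adjusted p = 0.00196). Rasgrp3 changed by -1.35, Cebpa by -1.17 and Rnd3 by -1.07. Il4i1 was at least 3.17-fold lower and the apoptosis gene Pmaip1 at least 1.55-fold lower, since both were not above background in IS.

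In all, 186 features passed, 77 higher and 109 lower, and 43 of them had a symbol. All 186 had the same sign in set A and in set B. They were chosen on both sets together, which favours such agreement, so it is no independent check. The median log2 fold change of the higher ones was 0.78 in set A and 0.97 in set B, and that of the lower ones -0.90 and -0.85. With the set as a block, 233 features passed. The groups did not overlap for 16% of features, where chance gives 10%. The count rested on single arrays: it was 91 without Control ACSF 1, 75 without Control ACSF 2, 118 without IS 1 and 85 without IS 2. It was 100 with ACSF + DIDS 2 grouped by its description and 38 with neqc on 9 arrays. Of the 17 named genes that passed, 12 passed with each array left out in turn, whereas Cebpa, Klf4, Mest, Rasgrp3 and Pmaip1 did not. Klf4 was lost without Control ACSF 1, Control ACSF 2, IS 1 or IS 2 (adjusted p up to 0.0703), and Cebpa when any 1 of 8 arrays was left out (up to 0.227). Of the 14 tested hypoxia-inducible factor targets, 0 passed by limma over all features and 1 had an unadjusted p under 0.05. That gene, Egln3, was the 1 that passed when adjusted over the list alone. As a list they were higher in limma's camera test (median 0.13, adjusted p = 0.0294), and not with an estimated correlation between genes (p = 0.935 after adjustment). With the set as a block the adjusted p was 0.0321.

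The comparison of IS + DIDS with IS asks what DIDS did to slices in the ischemic solution. Of the 11 tested immediate early genes, 7 fell. Many genes of that list, among them Fos, Jun, Egr1, Arc and Nr4a1, were not tested as named genes. Results for the list therefore cover only a part of it. The chemokine gene Cxcl1 showed the largest fall among the named genes, followed by Ccrl2 and Ptgs2. The transcription factor genes Klf4, Junb, Cebpb and Egr2 fell, as did Ccn1 and the survival gene Bcl2. Smaller rises were seen for Abi3, Klhl6, P2ry6 and Casp8, and for the ribosomal protein genes Rpl4 and Rpl36al.

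Cxcl1 changed by -4.75 (SE 0.60, adjusted p = 0.00195), by -5.48 in set A and -2.98 in set B. Its log2 intensity was 12.91, 12.72 and 10.01 on IS 1, IS 2 and IS 3. Cxcl1 did not pass the interaction test, unlike Ccrl2 and Ptgs2 (log2 difference -2.52, SE 0.85, adjusted p = 0.303). Ccrl2 changed by -4.59 (SE 0.46, adjusted p = 0.000531) and Ptgs2 by -3.01 (SE 0.41, adjusted p = 0.00309). Klf4 changed by -2.79 (SE 0.17, adjusted p = 1.25e-05) on its brightest probe, and by -0.50 (unadjusted p = 0.0674) on its dimmest. Junb changed by -1.63, Cebpb by -1.55, Btg1 by -1.42, and Ccn1, Egr2 and Irf1 by -1.35 each. Bcl2 changed by -1.05 (SE 0.10, adjusted p = 0.000502), and by -0.05 on a dim second probe. Homer2 changed by -0.64. Cytip was at least 3.56-fold lower, not above background in IS + DIDS (adjusted p = 7.71e-05). Abi3 rose by 1.29 (SE 0.21, adjusted p = 0.00847), Klhl6 by 1.15 (0.22 on a dim second probe, unadjusted p = 0.0614), Casp8 by 0.84, P2ry6 by 0.78, Rpl36al by 0.71, Tpt1 by 0.69, Rpl4 by 0.66 and Clta by 0.63.

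In this comparison 558 features passed, 131 higher and 427 lower, and 150 had a symbol. All 558, also chosen on both sets together, had the same sign in both, which is no independent check. The higher ones had a median of 0.60 in set A and 0.52 in set B, the lower ones -0.74 and -0.68, and 693 features passed with the set as a block. The groups did not overlap for 21.4% of features, where chance gives 10%. The count was 141 without IS 1, 281 without IS 2, 255 without IS + DIDS 2 and 242 without IS + DIDS 3. It was 102 with ACSF + DIDS 2 grouped by its description and 169 with neqc on 9 arrays. Of 21 named genes that passed, 11 passed with each array left out in turn. The others were Btg1, Casp8, Klhl6, P2ry6, Rpl36al, Rpl4, Tpt1, Clta, Homer2 and Irf1. Their largest adjusted p ran from 0.0527 for Rpl36al, lost without IS 1, to 0.158 for Btg1, which passed with only 2 of the 12 arrays left out.

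Of the immediate early genes, which cells switch on within minutes to hours of a stimulus, 9 fell in IS + DIDS against IS when adjusted over the list alone, and 7 over all features. Their median log2 fold change was -0.79 and camera gave an adjusted p of 8.64e-11, or 0.00297 with an estimated correlation. The mean of the list was -0.92 in set A and -0.90 in set B, and the adjusted p was 6.91e-09 with the set as a block. Of the 3 tested cytokine and chemokine genes, 1 passed, and 3 when adjusted over the list alone (camera adjusted p = 0.000159, 0.206 with an estimated correlation and 0.0013 with the set as a block).

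**Figure D2:**
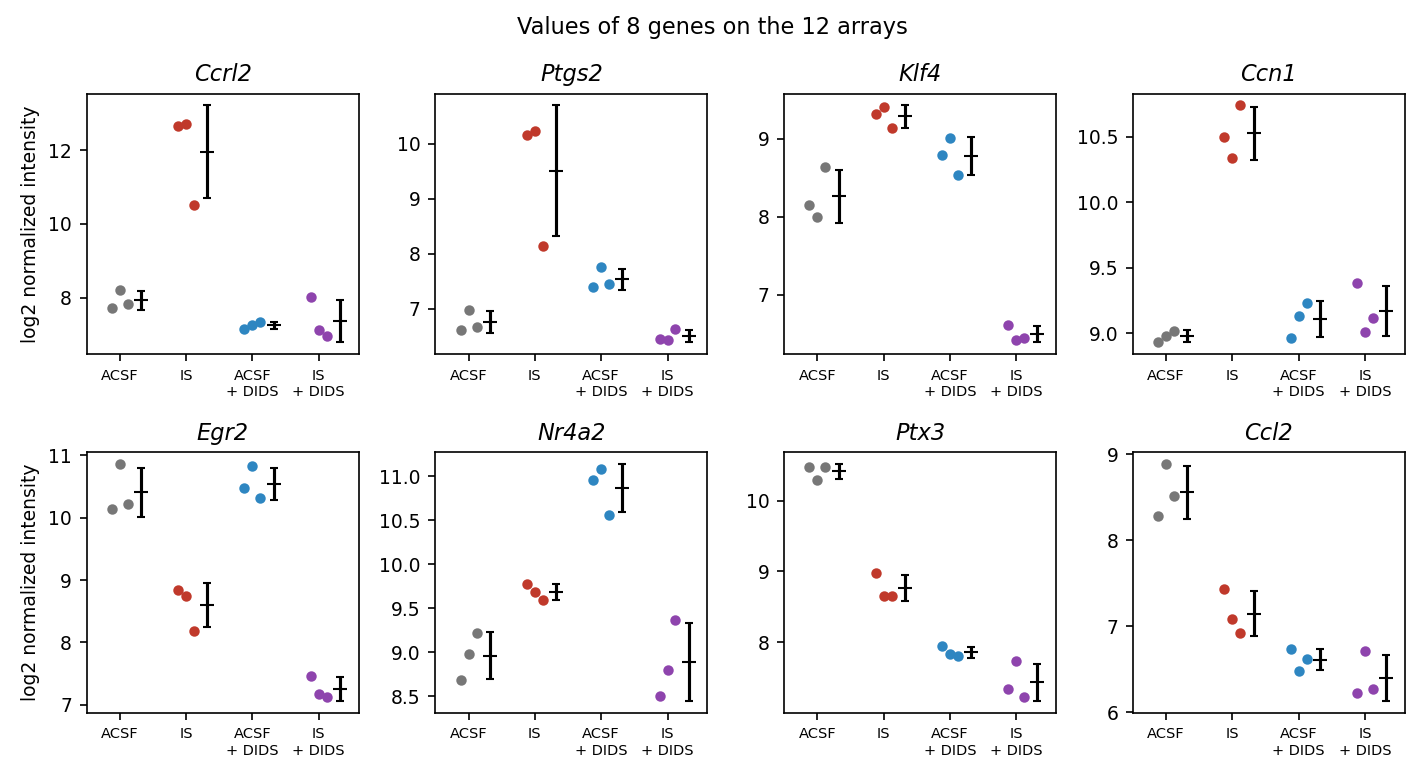
Log2 intensity of 8 named genes on each array (points, 3 per group), with bars for the mean and SD of each group. Ccrl2 and Ptgs2 were high on the IS arrays and low on the IS + DIDS arrays.

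The comparison of IS + DIDS with ACSF + DIDS asks what the ischemic solution did when DIDS was present in both arms. The early response transcription factor genes Egr2, Klf4, Nr4a2, Junb, Fosl2 and Nr4a3 fell. The oxidative stress gene Osgin1 and the lipid metabolism genes Insig1 and Stard4 fell as well. Id3, a regulator of transcription factors, and the hyaluronidase gene Hyal2 rose. Ccrl2 and Ccn1, which the ischemic solution raised without DIDS, did not pass here.

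Egr2 changed by -3.29 (SE 0.22, adjusted p = 1.96e-05), Klf4 by -2.29 (SE 0.17, adjusted p = 3.46e-05) and Nr4a2 by -1.98 (SE 0.21, adjusted p = 0.000451). The dimmest Klf4 probe changed by -0.03. Osgin1 changed by -1.60, Junb by -1.44, Fosl2 by -1.37, Nr4a3 by -1.36, Rasl10b by -1.35 and Insig1 by -1.22. Homer2 changed by -0.89, Stard4 by -0.87, Bcl2 by -0.84 (-0.23 on its dim probe) and Cenpa by -0.83, and Pmaip1 was at least 1.31-fold lower. Id3 rose by 1.53 (SE 0.20, adjusted p = 0.0018), Ephb4 by 1.20, Tipin by 1.09, Ccdc84 by 0.93, Plcd4 by 0.88, Hyal2 by 0.79, Slc31a2 by 0.75 and Med18 by 0.72. Ccrl2 differed by 0.11 and Ccn1 by 0.06.

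Here 437 features passed, 148 higher and 289 lower, and 113 had a symbol. All 437, again chosen on both sets together, had the same sign in both, which is no independent check. The higher ones had a median of 0.69 in set A and 0.53 in set B, the lower ones -0.84 and -0.72, and 756 features passed with the set as a block. The groups did not overlap for 24.4% of features, where chance gives 10%. The count was 287 without Control ACSF 1, 129 without ACSF + DIDS 1, 130 without ACSF + DIDS 2, 216 without ACSF + DIDS 3, 241 without IS + DIDS 1, 220 without IS + DIDS 2 and 285 without IS + DIDS 3. ACSF + DIDS 2 is described in its label as an IS + DIDS sample, against its title, and was grouped by title. Grouped by description, limma gave 0 features in this comparison, with 1852 at an unadjusted p under 0.05, and neqc on 9 arrays gave 39. Over 50 features ranked without this array, it lay at a median of 1.07 (quartiles 0.96 and 1.16) on a scale from 0 at the IS + DIDS mean to 1 at the mean of the other 2 ACSF + DIDS arrays. Of 23 named genes that passed, 12 passed with each array left out in turn. Ephb4, Tipin, Ccdc84, Plcd4, Slc31a2, Med18, Pmaip1, Insig1, Stard4 and Nr4a3 did not. Stard4 was lost without ACSF + DIDS 2 (adjusted p = 0.0505), and Pmaip1 whichever of the 12 arrays was left out (up to 0.15).

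Of the 11 immediate early genes, 8 fell in IS + DIDS against ACSF + DIDS, and 8 when adjusted over the list alone. Their median was -1.36 (camera adjusted p = 1.6e-10, or 0.00324 with an estimated correlation). The mean was -0.99 in set A and -1.23 in set B, and the adjusted p was 2.59e-09 with the set as a block. Synaptic vesicle and scaffold genes were lower as a list (median -0.19, adjusted p = 0.00591), and not with an estimated correlation (0.667). With the set as a block the adjusted p was 0.00357. Of its 12 genes 1 passed, Homer2, and 1 when adjusted over the list alone. This list's call was lost without IS + DIDS 1.

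**Figure D3:**
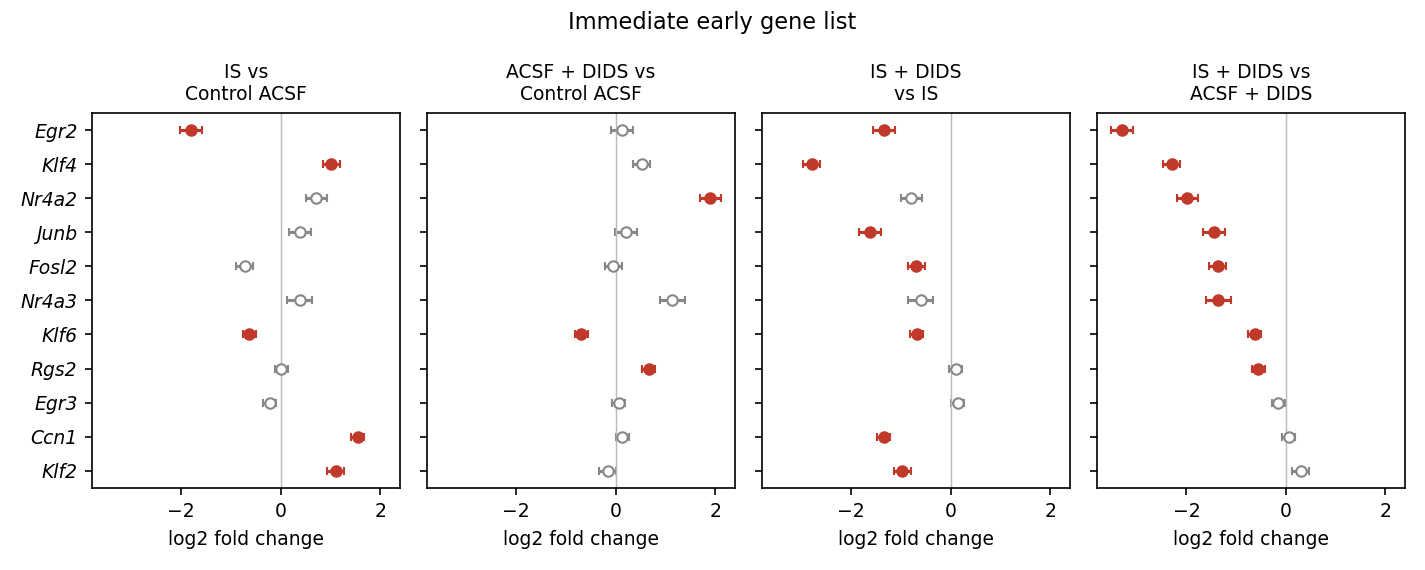
Log2 fold changes of the 11 tested immediate early genes in the comparisons of the groups. In IS + DIDS against ACSF + DIDS, 8 of the 11 fell, and Egr2 changed most, by -3.29.

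The comparison of ACSF + DIDS with Control ACSF asks what DIDS did without the ischemic solution. In artificial cerebrospinal fluid with DIDS, Ptx3, Ccl2, Irf1 and Il4i1 fell. Adamts1 and the receptor gene Tgfbr1 fell as well. The nuclear receptor gene Nr4a2, the oxidative stress gene Osgin1, the centromere gene Cenpa and Errfi1, a feedback inhibitor of growth factor receptors, rose.

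Ptx3 changed by -2.55 (SE 0.14, adjusted p = 3.73e-06), Ccl2 by -1.95 (SE 0.18, adjusted p = 0.000238) and Irf1 by -1.90 (SE 0.28, adjusted p = 0.00685). Il4i1 changed by -1.51, Adamts1 by -1.29, Trim47 by -1.11, Tgfbr1 by -1.04, Arid5a by -1.02 and Klf6 by -0.69. Nr4a2 rose by 1.90 (SE 0.21, adjusted p = 0.000723), Osgin1 by 1.12, Cenpa by 1.11, Errfi1 by 0.91, Msantd1 by 0.88 and Rgs2 by 0.66. In total 110 features passed, 33 higher and 77 lower, and 23 had a symbol. All 110, chosen in the same way on both sets, had the same sign in both, which is no independent check. The higher ones had a median of 1.06 in set A and 1.22 in set B, the lower ones -1.07 and -0.88, and 107 features passed with the set as a block. The groups did not overlap for 15.1% of features, where chance gives 10%. The count was 68 without Control ACSF 1, 64 without Control ACSF 2, 69 without ACSF + DIDS 1, 68 without ACSF + DIDS 2 and 65 without ACSF + DIDS 3. Grouping ACSF + DIDS 2 by its description gave 28, and neqc on 9 arrays 17. Of 15 named genes that passed, 10 passed with each array left out in turn. The others were Arid5a, Klf6, Rgs2, Osgin1 and Trim47. Their largest adjusted p ran from 0.102 for Trim47 to 0.172 for Arid5a and Klf6.

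Camera called 10 lists in ACSF + DIDS against Control ACSF with the preset correlation and 0 with the estimated one, with which 3 lists had an unadjusted p under 0.05. Lower were cytokines and chemokines (adjusted p = 4.37e-05, or 0.174 with an estimated correlation), interferon response genes (0.00302, or 0.303), Toll-like receptor signalling (0.026, or 0.303), microglia and macrophage markers (0.0393, or 0.602) and choroid plexus markers (0.0338, or 0.329). Higher were synaptic vesicle and scaffold genes (0.00195, or 0.329), hypoxia-inducible factor targets (0.00302, or 0.303), immediate early genes (0.0085, or 0.174), cation transport genes (0.0184, or 0.329) and neuron markers (0.0327, or 0.329). With the export set as a block, the microglial (adjusted p = 0.168), choroid plexus (0.0743), cation transport (0.0728) and neuron marker (0.0743) lists did not pass, and the other 6 did, at 0.000239 to 0.0448. Over all features, 2 immediate early genes rose and 1 fell, 1 cytokine gene (Ccl2) fell and 1 interferon response gene (Irf1) fell. Adjusted over the list alone, 5 immediate early genes, 2 cytokine genes, 1 interferon response gene, 2 Toll-like receptor signalling genes and 2 choroid plexus genes passed. In the other lists that camera called here, 0 genes passed either way in limma's test, and at an unadjusted p under 0.05 there were 3 hypoxia-inducible factor targets, 2 microglial, 1 synaptic, 1 cation transport and 0 neuron genes.

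The interaction asks whether DIDS changed the response to the ischemic solution, and compares IS + DIDS over ACSF + DIDS with IS over Control ACSF. The rises of Ccrl2, Ptgs2, Cytip, Arrdc3, Mest and Ccn1 without DIDS were not seen with it. Klf4 rose without DIDS and fell with it. Nr4a2 fell in the ischemic solution with DIDS only, and its response differed between the arms. That change of -1.98 started from a level that DIDS alone had raised by 1.9. Cenpa also rose with DIDS alone and fell in the ischemic solution with DIDS. Ptx3 and Il4i1 fell without DIDS, where DIDS alone had already lowered them.

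The response of Ccrl2 was lower with DIDS by a log2 difference of -3.92 (SE 0.66, adjusted p = 0.0217), that of Ptgs2 by -3.78 (SE 0.58, adjusted p = 0.0125), that of Klf4 by -3.31 (SE 0.24, adjusted p = 5.16e-05) and that of Nr4a2 by -2.69 (SE 0.29, adjusted p = 0.00152). On the dimmest Klf4 probe the difference was -0.57 (unadjusted p = 0.131). It was -1.84 for Junb, -1.60 for Arrdc3, -1.56 for Mest, -1.48 for Ccn1, -1.31 for Cenpa and -0.82 for Homer2. It was 1.53 for Trim47, 1.22 for Ptx3, 1.01 for Trex1 and 0.82 for Irgm2. Cytip and Il4i1 passed as well, but Cytip was not above background in both groups with DIDS and Il4i1 in IS, so no size is given for them. In all, 97 features passed, 33 higher and 64 lower, and 20 had a symbol. All 97, chosen in the same way on both sets, had the same sign in both, which is no independent check. Medians were 1.34 in set A and 1.12 in set B for the higher ones and -1.30 and -1.42 for the lower ones. With the set as a block 134 passed. The count was 45 without Control ACSF 1, 56 without IS 1, 57 without IS 2, 50 without ACSF + DIDS 1, 39 without ACSF + DIDS 2, 50 without IS + DIDS 2 and 62 without IS + DIDS 3. Grouping ACSF + DIDS 2 by its description gave 3, and neqc on 9 arrays 3. Of 16 named genes that passed, 7 passed with each array left out in turn. The others were Ccrl2, Ptgs2, Junb, Il4i1, Trim47, Ptx3, Trex1, Irgm2 and Homer2. Ptgs2 and Il4i1 were lost without ACSF + DIDS 2 (adjusted p = 0.0502 for each), and Ccrl2 when any 1 of 8 arrays was left out (up to 0.0745).

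Of the 11 immediate early genes, 4 had a lower response with DIDS, and 9 when adjusted over the list alone (median -1.47, camera adjusted p = 1.95e-14, or 0.00105 with an estimated correlation). The mean was -1.20 in set A and -1.32 in set B, and the adjusted p was 1.23e-12 with the set as a block. The list of synaptic vesicle and scaffold genes was lower (0.00803, or 0.63 with an estimated correlation) and that of microglia and macrophage markers higher (0.00364, or 0.63). Both lists had an adjusted p of 0.00407 with the set as a block, and both calls were lost without IS + DIDS 1. Among the synaptic genes 1 passed, and 1 when adjusted over the list alone. Among the 10 microglial genes 0 passed by limma over all features, 1 passed when adjusted over the list alone and 2 had an unadjusted p under 0.05.

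Across the 186 features that the ischemic solution changed without DIDS, the slope of the response with DIDS on that without it was 0.13 (jackknife SE over arrays 0.12), with Pearson's r 0.19 and Spearman's rho 0.38. The relation is across features, which are not independent replicates. Of the 186, 72.6% had the same sign in both arms, 34 also passed with DIDS in the same direction and 5 in the opposite one. Selecting features on the first response lowers this slope by itself. Over all 20749 features the slope was 0.28 and r was 0.23.

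**Figure D4:**
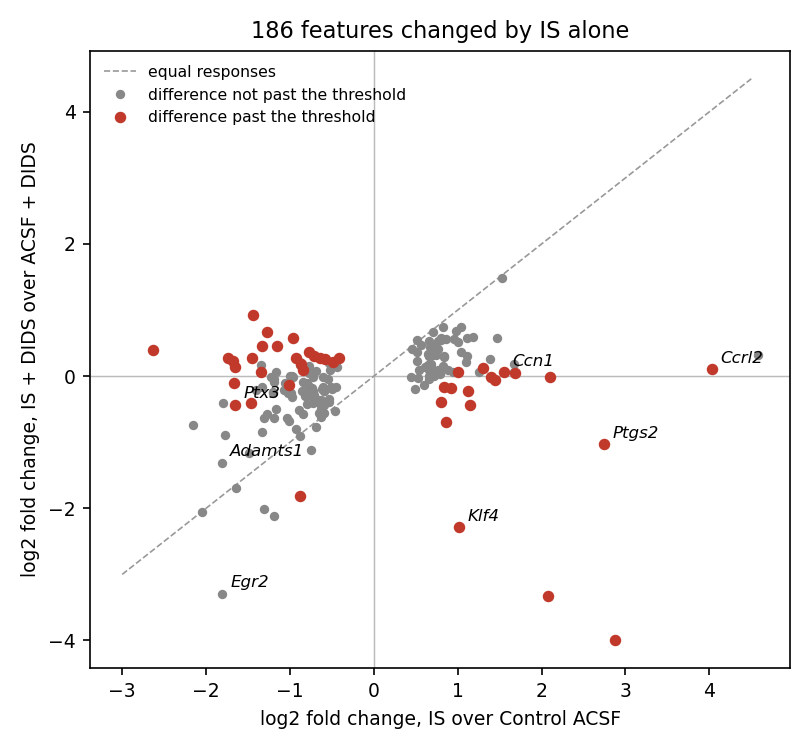
Log2 fold change of IS + DIDS over ACSF + DIDS against that of IS over Control ACSF for the 186 features changed by IS alone. Red points passed the interaction test, and the dashed line marks equal responses.

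Of the 77 features that rose in IS, 41 fell in IS + DIDS against IS, where independent lists would share 1.6. Over all features the covariance of these 2 comparisons was -0.019, against -0.0155 in simulated unchanged groups that share the IS arrays. Arrdc3, Klf4, Mest, Ptgs2, Ccn1, Klf2, Cytip and Ccrl2 were among the 41. The 41 became 24 without Control ACSF 1, 26 without Control ACSF 2, 23 without IS 1, 20 without IS 2, and 26 without IS + DIDS 2 or IS + DIDS 3. A further 16 features fell in IS and were higher in IS + DIDS. Ptx3, Ccl2, Il4i1 and Adamts1 fell in IS and in ACSF + DIDS against the same controls, as did 39 features in all, where independent lists would share 0.4. The covariance of these 2 comparisons was 0.0194, against 0.0153 in simulated unchanged groups with the same controls, so part of that overlap may come from the shared arrays.

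The remaining gene lists had adjusted p-values of 0.062 to 0.986 in IS against Control ACSF, 0.0544 to 0.963 in IS + DIDS against IS, and 0.172 to 0.89 in IS + DIDS against ACSF + DIDS. In ACSF + DIDS against Control ACSF they ranged from 0.0571 to 0.963, and in the interaction from 0.0572 to 0.985. Neuron markers had medians of -0.02, 0, -0.21 and 0.25 in the comparisons of IS with Control ACSF, IS + DIDS with IS, IS + DIDS with ACSF + DIDS, and ACSF + DIDS with Control ACSF. Tlr2, Fos, Hspa1a, Hmox1, Vegfa, Il1b and Slc2a1, fixed in advance to be given in every comparison, had no named probe.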

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

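The 5 tests of other splits and the test without IS + DIDS 1 were set before their results were seen; the tests of the shared IS arrays, that of DIDS alone, the 2 of neuron share and that of the label of ACSF + DIDS 2 were set after.

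A difference between the responses to the ischemic solution with and without DIDS passed the interaction test for 97 features. It was -3.92 for Ccrl2, -3.78 for Ptgs2, -3.31 for Klf4, -2.69 for Nr4a2, -1.84 for Junb, -1.60 for Arrdc3, -1.56 for Mest, -1.48 for Ccn1, -1.31 for Cenpa and -0.82 for Homer2 on the log2 scale. It was 1.53 for Trim47, 1.22 for Ptx3, 1.01 for Trex1 and 0.82 for Irgm2. Cytip (adjusted p = 0.00299) and Il4i1 (0.014) passed too, but Cytip was not above background in both groups with DIDS, nor Il4i1 in IS, so no size is given. Among the gene lists, the response differed for immediate early genes (camera adjusted p = 1.95e-14), for synaptic vesicle and scaffold genes (0.00803) and for microglia and macrophage markers (0.00364). The latter 2 were lost with an estimated correlation and without IS + DIDS 1.

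Of 100 splits of the 12 arrays into 4 groups of 3, 1, the real one, gave as many as the 97 features of the interaction. The highest of the others gave 9. With the arrays grouped by title, random labels thus did not reach this count. Such splits mix groups that differ, which widens the spread within groups. They do not test groups that differ without an interaction, so chance is not excluded for it. With ACSF + DIDS 2 grouped by its description, or with neqc on 9 arrays, 3 features passed, a count that some of the other splits reached, and these settings were not tested against splits of their own. The values of ACSF + DIDS 2 argue against its description: over 50 features ranked without it, its median position was 1.07 (quartiles 0.96 and 1.16), where 0 is the mean of IS + DIDS and 1 that of the other 2 ACSF + DIDS arrays. Placed in the same way, the other 2 lay at 0.93 and 0.88 and the IS + DIDS arrays at 0.02 to 0.09. Within set B its position was 0.46 (quartiles 0.25 and 1.06), but there the ranking rests on ACSF + DIDS 3 alone. The comparisons of 2 groups allow 10 splits of their 6 arrays, too few for a share under 0.05. In each of them 1 split, the real one, reached the count. IS against Control ACSF had 186 features against 0 in the highest other split, and IS + DIDS against IS had 558 against 0. IS + DIDS against ACSF + DIDS had 437 against 1, and ACSF + DIDS against Control ACSF had 110 against 0.

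The first pattern is that 41 features rose in IS and fell again in IS + DIDS. Chance values of the IS arrays, which enter both comparisons, would produce such a reversal, but the 50 features ranked highest on 1 IS array over Control ACSF also fell from the other 2 IS arrays to IS + DIDS, with medians over features of -1.09, -1.09 and -0.42 for rankings on IS 1, IS 2 and IS 3 (quartiles of the last -1.14 and -0.01), while an earlier test across the export sets, with -0.88, rests on IS 3 alone. DIDS alone did not lower the 41 by as much: their median was 0.09 in ACSF + DIDS over Control ACSF (quartiles -0.16 and 0.23) against -0.89 in IS + DIDS over IS. The 41 were selected on the same controls, but 50 features ranked with 1 control array had medians of -0.08, 0.12 and -0.16 for DIDS alone over the other 2. That DIDS blocks these rises may hold for part of them, as a hypothesis found and tested on the same arrays: 17 of the 41 passed the interaction, probes scl53482.9.1_175-S (4.53) and scl31688.5.1_17-S (2.23) among them rose with DIDS alone, and the 41 became 26 with ACSF + DIDS 2 grouped by its description and 12 with neqc on 9 arrays.

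The second pattern is the fall of immediate early genes in IS + DIDS, with a median of -0.79 against IS and -1.36 against ACSF + DIDS. A lower share of neurons would lower neuron markers by a like amount, but their median was 0 against IS and -0.21 against ACSF + DIDS. The array IS + DIDS 1 alone is not the source, since the median against IS was -0.75 without it. A lower response of these genes to the ischemic solution with DIDS may be a candidate explanation, as a hypothesis. The list passed the interaction test (camera adjusted p = 1.95e-14). Within it, Klf6 changed by -0.68 against IS with an interaction of 0.01. DIDS without the ischemic solution raised Nr4a2 by 1.9. By camera the whole list was also higher in ACSF + DIDS against Control ACSF, a call kept in 27 of 29 alternatives. It was lost with an estimated correlation (adjusted p = 0.174) and with ACSF + DIDS 2 grouped by its description. Members went both ways there, with Rgs2 higher and Klf6 lower. This effect of DIDS alone was not tested as a source of part of the pattern. The list kept its call under each normalization tried, in both comparisons, while a loss of the particular cells that express these genes was not tested.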

How the results depend on the processing

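Tests on the 9 arrays with neqc or with deposited values, normexp correction, a second quantile normalization and the export set as a block without IS + DIDS 1 were chosen after seeing the data.

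Counts below are in the order IS against Control ACSF, IS + DIDS against IS, IS + DIDS against ACSF + DIDS, ACSF + DIDS against Control ACSF, and the interaction, where 186, 558, 437, 110 and 97 features passed. Leaving out each array in turn gave 75 to 270, 141 to 549, 129 to 483, 64 to 152 and 39 to 113. With ACSF + DIDS 2 in the IS + DIDS group, limma gave 100, 102, 0, 28 and 3, and for the 0 there were 1852 features at an unadjusted p under 0.05. Scanner values of 9 arrays gave 209, 59, 64 and 27 in the latter 4 with quantile normalization, and 99, 255, 28, 10 and 26 with background correction and median scaling. With neqc they gave 38, 169, 39, 17 and 3. The deposited values of the 9 arrays gave 101, 243, 83, 73 and 32, so fewer arrays account for part of this. Fitting only the 2 groups gave 120 in IS + DIDS against IS and 135 in IS + DIDS against ACSF + DIDS, with fewer arrays to estimate the spread. A 1.5-fold threshold gave 366 in IS + DIDS against IS. The export set as a block gave 756 in IS + DIDS against ACSF + DIDS, and without IS + DIDS 1 it gave 348 in IS against Control ACSF and 300 in IS + DIDS against IS. Probes detected on all 9 arrays gave 71 in ACSF + DIDS against Control ACSF. Where no reason is given, the cause was not tested.

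The share of lower calls moved on the 9 scanner files, where the number of arrays, the source of the values, background correction and scaling change together, so the cause is not known, and some shares rest on few calls. It was 58.6%, 76.5%, 66.1%, 70.0% and 66.0% as reported, 15.2%, 94.1%, 89.3%, 30.0% and 96.2% with median scaling, and 47.4%, 61.5%, 71.8%, 29.4% and 100% with neqc. With quantile normalization of scanner values it was 91.5% in IS + DIDS against ACSF + DIDS and 85.2% in the interaction.

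The slope of the response was 0.13, with 0.05 to 0.18 over arrays left out and 0.36 with neqc. Of the gene lists, 18 were called, 11 to 23 with an array left out (11 without Control ACSF 1), and 3 with an estimated correlation. Immediate early genes kept their call in all 29 alternatives in IS + DIDS against IS (largest adjusted p = 0.00297) and against ACSF + DIDS (0.00324), and in all 28 in the interaction (0.00105). The 41 features that rose and then fell were 12 to 49 over the alternatives, 12 with neqc.

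Of 2687 values of named genes under the alternatives, 2118 kept their direction and side of the threshold, 569 kept direction only, and 0 reversed. Of 92 gene calls, 9 passed in every alternative: Adamts1, Arrdc3, Ccn1, Klf2 and Ptx3 in IS against Control ACSF, Ccn1 and Cebpb in IS + DIDS against IS, Ptx3 in ACSF + DIDS against Control ACSF and Ccn1 in the interaction.

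The values do not settle whether replicate numbers pair the samples. Same-numbered arrays had a median correlation of deviations of 0.11 (18 pairs, -0.30 to 0.40), with 9 over 0.1. Other-numbered arrays had a median of -0.06 (36 pairs), also with 9 over 0.1. The median was 0.11 within an export set and -0.08 across sets, and number and set overlap. Of 12 arrays, 1 correlated best with its own number in all other groups. A replicate block gave 174, 637, 479, 129 and 100 features and changed no count by more than 1.5 times. Under the replicate block 8 named calls were lost: Cebpa in IS against Control ACSF, Tipin, Ccdc84, Slc31a2 and Med18 in IS + DIDS against ACSF + DIDS, Rgs2 in ACSF + DIDS against Control ACSF, and Trex1 and Irgm2 in the interaction. The planned use of the value table as an alternative is the fit reported here. A test of scanner values on all 12 arrays was not run because 3 files hold signals of other arrays. Signal over background limits what the arrays show, since 40.3% to 45.5% of probes were detected.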

Other observations

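The test of bright features on IS + DIDS 1 was set before its result was seen, and the tests of cell mix, of ribosomal protein genes and of mitochondrial transcripts were set after, with criteria that were revised once their results were known. Under the first criteria, the values counted against another cell mix, for a joint rise of ribosomal protein genes and for a joint fall of mitochondrial transcripts; the revised criteria leave all 3 undecided.

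The third pattern is that IS + DIDS 1 stood apart, with a mean correlation of 0.983 with the other arrays, against 0.989 to 0.991 for those. Weak or noisy hybridisation would widen the spread of dim features above all, but over the 5085 bright features the spread of this array's deviations was 1.69 times the median of the 9 arrays of the other groups (0.376 against 0.223). It was 1.56 times over the 9553 dim features. IS + DIDS 1 is also the only array of its group in set A. Other arrays alone in their set had spreads over bright features of 0.297 (Control ACSF 3), 0.279 (IS 3) and 0.223 (ACSF + DIDS 1). The ratios may therefore include a difference between sets, which was not tested as a cause. Another mix of cell types in that culture cannot be told apart from other causes: its microglia and macrophage markers lay 0.51 above the other 2 arrays of its group, against at most 0.35 in size on the 9 arrays of the other groups, but those of IS + DIDS 3 lay further off, at -0.63, so the list does not single out IS + DIDS 1. Astrocyte markers lay 0.33 above (at most 0.21 on the 9 arrays), against -0.26 on IS + DIDS 3, and neuron markers lay at -0.20, within the 0.28 of the 9 arrays. No other biological explanation was tested, since the design names none for a single array.

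Over all 70 named genes of ribosomal proteins, the list was higher in IS + DIDS against IS (median 0.06, camera adjusted p = 0.00388 over the 4 comparisons), and not with an estimated correlation (p = 0.276). Against ACSF + DIDS the median was 0.15 (adjusted p = 2.9e-05, and p = 0.129 with an estimated correlation). Rpl4 and Rpl36al were the 2 genes that passed against IS. Whether these genes rise together is not decided by these values.

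Over the 12 probes named for mitochondrial DNA, the list was lower in IS against Control ACSF (median -0.07, camera adjusted p = 0.0361), and not with an estimated correlation (p = 0.263). The ND3 probe, mtDNA_ND3-S, was the only 1 of the 12 to pass, with a log2 fold change of -1.04 (adjusted p = 0.00173). It was also lower in IS + DIDS against ACSF + DIDS, by -0.64 (adjusted p = 0.0295).

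Some of the largest changes were of probes without a symbol. Probe scl18674.7.1_35-S rose by 4.58 in IS over Control ACSF and changed by -5.45 in IS + DIDS over IS. Probe scl53482.9.1_175-S rose by 2.88 in IS and by 4.53 in ACSF + DIDS over Control ACSF, and changed by -3.99 in IS + DIDS over ACSF + DIDS. Probe scl52539.1_152-S changed by -2.63 in IS over Control ACSF and rose by 2.21 in IS + DIDS over IS.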
